A study of Mus musculus with 18 samples.

How the data were processed

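The samples were 18 libraries of poly(A) RNA from the rectus femoris, a thigh muscle, of C57BL/6 mice, sequenced as paired-end reads. Per the labels they fell into 3 arms of 6 libraries, each with 3 females and 3 males: young untreated mice of 8 months, old untreated mice of 19 months, and old mice of 19 months given 3TC. 3TC (lamivudine) is a nucleoside inhibitor of reverse transcriptase; the labels give 2 mg per mL in the drinking water for 6 weeks. The submitters' processing notes name STAR for the alignment and mm10 as the genome. The program and annotation behind the transposable-element values were not given in the sources used here.

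The deposited values were normalised counts: the authors had scaled each library's read counts to a common total of 74.0 M counts, and this signal was used as deposited. All values of each library were whole multiples of a single step (100% within a tolerance of 0.001 reads), so the read counts could be recovered, and they came to 64.2 M to 85.4 M per library. For the old untreated female 1 and the young untreated male 1 the step lay near 1, which leaves the recovered counts close to the deposited ones. The table held 25604 rows, of which 24431 were genes, 1146 were transposable-element subfamilies and 27 carried dates in place of gene symbols. The rows with dates held 0.0628 to 0.0831% of the counts and were left out of the tests, and 2817 rows were at 0 in every library. The 37 mitochondrial transcripts were renamed from their identifiers, and coordinates came from the GENCODE annotation of GRCm38, the assembly also called mm10. All 18 columns were mapped to a library. The column of young untreated female 1 carries replicate number 2 in its own name, and its place in the arm and its sex followed the labels.

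Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2 of the normalised count plus 1, for the 16060 gene rows with a mean of at least 10 over the 18 libraries. The columns hold scaled values and not raw counts, so limma was used, with edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads as alternatives. The model held arm and sex and left 14 residual degrees of freedom. Changes within a sex and differences between the sexes came from a model with the 6 combinations of arm and sex. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 changes are standard errors (SE) from limma, and errors of means are standard deviations (SD) between libraries.

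Gene groups came from 49 fixed lists with 1270 members, of which 1255 were found. They were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and over lists with at least 5 tested members. Adjusted p values of lists are over the 49 lists of a comparison. Each list was also tested with the correlation between its genes estimated from the data, with fry, and with a score per library under an exact two-sided permutation of the arm labels within sex (400 regroupings, smallest p 0.005). Shares of counts were compared by an exact two-sided permutation test over 924 regroupings, with a smallest possible p of 0.00216. The 968 transposable-element subfamilies with a mean of at least 10 were tested with the same limma model, as an analysis added after the data were seen.

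The arms, the comparisons, the tests, the lists, the first set of alternatives and the rule for the genes to be named were set before the data were examined. The rule took the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 50, the same sign in both sexes and a symbol that is not a predicted name. Where fewer than 5 passed in a direction, it took up to 5 genes with the smallest p in that direction. It added the 4 members with the smallest p of each list called and 25 genes named in advance. For the remaining comparisons it took up to 3 genes in each direction.

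Alternatives were median-of-ratios scaling, quantile normalisation, other pseudocounts and filters, no trend, array weights, edgeR, DESeq2, arms fitted in pairs, no sex term, a replicate block, other thresholds and leaving out each library. Alternatives added after the data were seen were leaving out young untreated females 1 and 3, tissue scores as covariates, a total over gene rows only, a list score per library and edgeR without the pair of libraries whose step lay near 1.

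The method was tested on simulated data with changes planted in the real spread. For the age comparison limma found 37.3% of genes planted at 1.5-fold, 67.2% at 2-fold and 87.9% at 4-fold. For 3TC these shares were 28.4%, 55.2% and 83.3%. For a difference between the sexes in the age change, 19.4% were found at 2-fold. False calls by limma were 7 of 135 for age, 4 of 115 for 3TC, 15 of 131 for old 3TC against young and 8 of 97 for age in females. These shares are for 67, 67 and 66 genes planted at the 3 folds, and may be lower where fewer genes change. The simulated libraries held no liver or brain RNA that differs between libraries. A planted list was called by camera at adjusted p = 3.996e-13, and 0 of 48 random lists were called. The simulated genes were drawn independently of each other. This therefore cannot tell how the preset correlation fares on lists whose genes vary together, such as macrophage markers (estimated correlation 0.61) or complex I genes (0.84). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.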

Results

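Gene expression was measured by RNA sequencing in the rectus femoris of 6 young untreated mice (8 months), 6 old untreated mice (19 months) and 6 old mice (19 months) given the reverse transcriptase inhibitor 3TC in their water for 6 weeks. Each arm held 3 females and 3 males. The libraries held 64.2 M to 85.4 M recovered reads. The series asks what aging does to this muscle and what 3TC does in old muscle. Values are normalised read counts, given as mean ± SD with n = 6 libraries per arm, and changes are log2 changes ± SE from limma.

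Sex-linked genes matched the labels in all 18 libraries. Xist, the RNA of the inactive X chromosome, stood at 10000 ± 1940 normalised counts in the 9 females and at 8 ± 5.08 in the 9 males. The Y-linked demethylase gene Kdm5d stood at 0 in the females and at 668 ± 88 in the males.

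Some libraries held transcripts of other organs. A score of 22 liver genes, the mean of log2 of the normalised count plus 1, averaged 8.98 ± 2.63 in young, 5.30 ± 3.68 in old untreated and 5.77 ± 4.95 in old 3TC libraries. It was highest in old 3TC male 2, at 12.92, where Alb, the gene of serum albumin, had 190525 normalised counts, and lowest in old untreated male 3, at 1.51. A score of 16 brain genes averaged 4.03 ± 2.73, 4.31 ± 3.19 and 2.09 ± 1.68 in the same order, and was highest in young untreated male 8, at 8.94. Within sex, the liver score of old untreated libraries differed from that of young ones by −3.68 (n = 6 each, exact two-sided permutation p = 0.01 over 400 regroupings), and all 3 old untreated males lay below every young male. The brain score differed by 0.28 (exact permutation p = 0.875). With 3TC the liver score differed by 0.47 and the brain score by −2.22 (exact permutation p = 0.895 and 0.095). The gene lists of both scores and these tests were written after these transcripts had been seen.

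**Figure D1:**
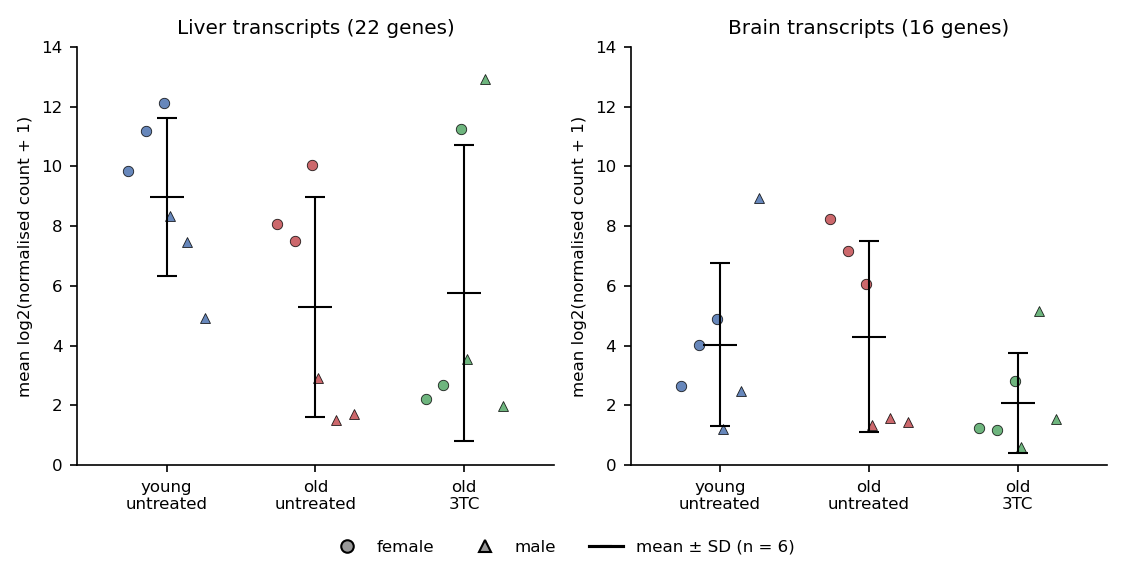
Mean log2 of the normalised count plus 1 over liver genes (left) and brain genes (right) in each library, by arm. Circles are females, triangles are males and bars are mean ± SD (n = 6); the liver score of old 3TC libraries runs from 1.99 to 12.92.

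Among called genes with a mean of at least 50, those that rose most with age in untreated muscle included several known from immune cells. The chemokine gene Ccl8 (chromosome 11, 82115185 to 82116799) rose from 26 ± 21.8 to 219 ± 167 normalised counts, a 10.7-fold change (log2 3.42 ± 0.63, adjusted p = 0.0294, limma). Other such genes were Hpgds, a prostaglandin D synthase (1.81 ± 0.29), Spn, the sialoprotein CD43 (1.79 ± 0.31), Sash3, a lymphocyte adaptor (1.54 ± 0.28), and Cysltr1, a leukotriene receptor (1.46 ± 0.31). Wfdc17 (1.85 ± 0.33), Dennd1c (1.42 ± 0.25), Gmfg (1.32 ± 0.27) and the myosin gene Myo1g (1.28 ± 0.27) completed the 10 largest increases under the naming rule with Car3. Car3 is a carbonic anhydrase of adipocytes and muscle (1.48 ± 0.28, 43500 ± 36900 to 106000 ± 69000). Called genes with a mean under 50, which the rule left out, included Gm7609 (4.54 ± 0.68), Nkx2-2os (3.28 ± 0.63), Bcl2a1b (2.99 ± 0.6), Rasal3 (2.51 ± 0.52) and Tnfsf13b (1.47 ± 0.29). The genes that fell were Nr4a1 (chromosome 15, 101254269 to 101274795), an orphan nuclear receptor of the immediate early response, from 14400 ± 2360 to 8840 ± 2750 (fell by 0.75 on the log2 scale, SE 0.14), and Sgk1, a kinase induced by glucocorticoids, from 8820 ± 1500 to 5630 ± 1230 (fell by 0.66, SE 0.13). Gadd45g (−0.78, adjusted p = 0.0551, limma), Slc25a25 (−1.42, adjusted p = 0.0597) and Tsc22d3 (−0.55, adjusted p = 0.0625) did not pass.

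Of 16060 genes tested, limma called 59 for age, 57 higher and 2 lower in old mice. At an unadjusted p under 0.05 by limma there were 3538 genes, where chance gives 803. In 57 of the 59, all 6 old libraries lay on the side of the change from the young mean, and in the others 5 did. The 59 genes were chosen from these same libraries, so this adds no separate support. The median of all genes lay 0.16 above 0 on the log2 scale with age, and at 0 under median-of-ratios scaling. That scaling called 24 genes, 16 higher and 8 lower, so the excess of increases depends in part on the scaling. With only the young and old untreated arms in the fit, 40 genes passed, 12 higher and 28 lower, of which 10 were among the 59, so the excess turned to decreases. The count rested on single libraries: it fell to 2 without old untreated male 1 or young untreated male 1, to 4 without old untreated male 6 or young untreated female 3, and to 6 without old untreated male 3. It was 11 without young untreated male 2, 12 without old untreated female 1 or young untreated female 1, 14 without old untreated female 2, 268 without old untreated female 3, 606 without young untreated female 8 and 608 without young untreated male 8. Without young untreated females 1 and 3 together, whose transposable-element share stood apart, the count was 2. Adding the liver score, which differed with age, and the brain score as covariates left 4 genes called by limma. By edgeR 4 genes passed and by DESeq2 221.

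**Figure D2:**
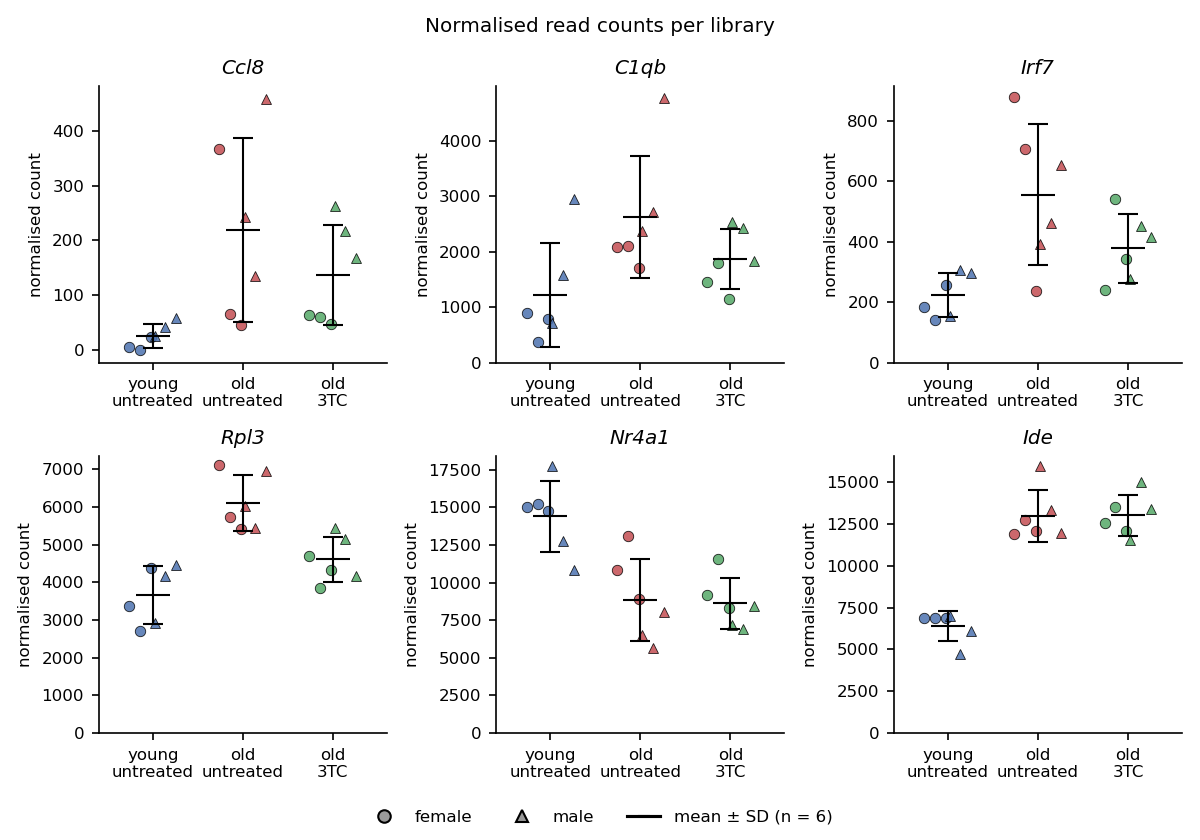
Normalised read counts of 6 genes in each library, by arm. Circles are females, triangles are males and bars are mean ± SD (n = 6); Ccl8 averages 26 in young and 219 in old untreated mice, and Nr4a1 falls from 14400 to 8840.

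Several lists of immune genes moved up with age by camera at the preset correlation, whereas no list passed for age with an estimated one. Members adjusted over the list alone were tested against 0, so their counts include the shift of all genes (median 0.16). Of all 16060 genes, 3538 had an unadjusted p under 0.05 for age by limma. Such counts therefore do not set a list apart by themselves. T and NK cell markers and B and plasma cell markers (camera adjusted p = 0.0614 each) and NF-kB and acute inflammatory genes (0.329) were not called. All 26 macrophage markers lay above the all-gene median, by 1.03 at their median (adjusted p = 9.52e-13, or 0.569 with an estimated correlation), and 25 rose when adjusted over the list alone, with 0 past the threshold over all genes. Complement genes lay 0.66 above it (adjusted p = 1.97e-08), with 18 of 21 risen when adjusted over the list alone, such as C1qb at 1.35 ± 0.29 (adjusted p over all genes = 0.0509, limma) and C4a at 1.39, which shares reads with the near-identical C4b. Of 18 genes of MHC class I presentation, 15 rose when adjusted over the list alone and 3 over all genes: H2-T23 (1.00 ± 0.19), Psmb10, an immunoproteasome subunit (0.64 ± 0.13), and H2-T22 (0.61 ± 0.11), with a list median 0.57 above all genes (adjusted p = 6.63e-09). Of 40 interferon-stimulated genes, 27 rose when adjusted over the list alone, with the list 0.61 above all genes (adjusted p = 1.46e-08). Irf7, a regulator of interferon genes, went from 222 ± 72.9 to 555 ± 234 (1.26 ± 0.30, adjusted p = 0.0564, limma) and Ifi204 changed by 0.78, neither past the threshold over all genes. MHC class II genes (9 of 10 adjusted over the list alone, H2-Aa 1.18, Cd74 1.04, list adjusted p = 0.000407), genes of nucleic acid sensing in the cytosol and in endosomes (12 of 24, Tlr9 1.61 ± 0.39, list adjusted p = 0.000496) and neutrophil markers (7 of 10, S100a8 2.52 ± 0.70, Mmp9 0.84, list adjusted p = 0.0295) moved the same way. The estimated correlation gave adjusted p = 0.569 for complement and neutrophil genes too and adjusted p = 0.642 for the other called lists named here. The exact two-sided permutation of scores per library called 5 lists at adjusted p = 0.049, namely interferon-stimulated, nucleic acid sensing, complement, senescence and myokine genes, where camera gave adjusted p = 0.392 for senescence and 0.405 for myokines. Each of these 5 had the smallest p that this permutation allows, 0.005. Their shared adjusted p is therefore set by the number of lists at that floor. The neutrophil call was lost in 3 of 18 fits that left out a library, with the highest adjusted p, 0.101, without old untreated female 3. The other immune lists called by camera kept their calls in all 18.

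Cytosolic ribosomal protein genes rose together by a small amount: 49 of 50 passed when adjusted over the list alone and 1 over all genes, Rpl3, from 3670 ± 768 to 6110 ± 751 (0.75 ± 0.13). Their median lay 0.10 above all genes (camera adjusted p = 7.63e-18, or 0.642 with an estimated correlation). Their score per library gave an exact two-sided permutation p of 0.155. Adipocyte markers lay 0.82 above all genes, with 1 of 27 past the threshold, Car3 (adjusted p = 0.0104), fibroblast markers 0.29 above, with 5 of 25 risen when adjusted over the list alone (Fbln1 0.84, Lox 0.96, adjusted p = 0.0104), and autophagy genes 0.02 above, with 8 of 26 (Uvrag 0.47, Map1lc3a 0.39, adjusted p = 0.0104). With an estimated correlation these gave adjusted p = 0.766. Adipocyte markers gave adjusted p = 0.23 without old untreated female 2, fibroblast markers 0.0921 without old untreated male 6 and autophagy genes 0.0768 without young untreated male 2. Without young untreated females 1 and 3 the adjusted p was 0.186 for adipocyte and 0.066 for fibroblast markers, and under median-of-ratios scaling it was 0.237 for autophagy genes. The covariates gave adjusted p = 0.132 for fibroblast markers.

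Genes of fast fibres, respiration, the TCA cycle and glycolysis lay below the all-gene median with age. Slow fibre genes (0.26) and fatty acid oxidation genes (0.06) lay above it and were not called by camera (adjusted p = 0.392 and 0.41). Genes of fast muscle fibres lay below it by −0.27 at their median (camera adjusted p = 5.33e-06; adjusted p = 0.569 with an estimated correlation), with Myl1 at −0.50 and Casq1 at −0.47 and 0 of 16 past the threshold or past it when adjusted over the list alone. Immediate early genes lay at −0.23 (camera adjusted p = 2.55e-08; adjusted p = 0.569 with an estimated correlation), with Nr4a1 fallen, 2 of 27 fallen when adjusted over the list alone, and Nr4a2 at −1.62 ± 0.40. Nuclear genes of respiratory complex I (−0.17, adjusted p = 0.000496) and of complexes II to V (−0.14, adjusted p = 0.00182), TCA cycle (−0.15, adjusted p = 0.0295) and mtDNA-encoded genes (−0.16, adjusted p = 0.0263) also lay below, each with 0 members past the threshold by either adjustment and adjusted p = 0.766 with an estimated correlation. Their own medians were between 0 and 0.02 under the deposited scaling, so they lay below the other genes without falling as sets. Under median-of-ratios scaling, which removes the all-gene shift, camera still called complex I (adjusted p = 0.000265), complexes II to V (0.00227) and the TCA cycle (0.00456) below. Among the members with the smallest p were Ndufa7 (0.12), Cox8a (0.45), Sdha (0.09), Ogdh (0.28), Suclg2 (0.12), mt-Nd3 (0.16) and mt-Rnr2 (−0.22). Glycolysis genes lay at −0.18 (Slc2a1 0.36, Pgm1 0.41, list mean 0.05, adjusted p = 0.0109), myogenic genes at −0.09 (Pax7 −0.76 ± 0.27, Myf5 −0.78, list mean 0.11, adjusted p = 0.0263), clock genes at −0.04 (Per1 −0.52, list mean 0.03, adjusted p = 0.0235) and calcium-handling genes at −0.11 (Camk2d 0.32, Camk2b 0.27, list mean 0.06, adjusted p = 0.0276). These 4 lists had 0 members past the threshold by either adjustment and gave adjusted p = 0.642 with an estimated correlation, or 0.766 for calcium handling. The calls of complex I, complexes II to V and all lists after them in this account were lost in 2 to 6 of the 18 fits that left out a library. Without young untreated male 2, whose mtDNA-encoded share was the highest, the adjusted p was 0.376 for complex I, 0.655 for complexes II to V, 0.653 for the TCA cycle and 0.778 for mtDNA-encoded genes. The highest adjusted p was 0.137 for glycolysis without old untreated female 1, 0.0956 for myogenic and 0.0807 for clock genes without old untreated female 2, and 0.188 for calcium handling without old untreated male 6. With the liver and brain scores as covariates the adjusted p was 0.106 for the TCA cycle, 0.0681 for myogenic and 0.161 for calcium-handling genes. Leaving out young untreated females 1 and 3 gave 0.0525 and 0.276 for the latter pair. Under median-of-ratios scaling it was 0.0722 for mtDNA-encoded, 0.174 for myogenic and 0.114 for clock genes.

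**Figure D3:**
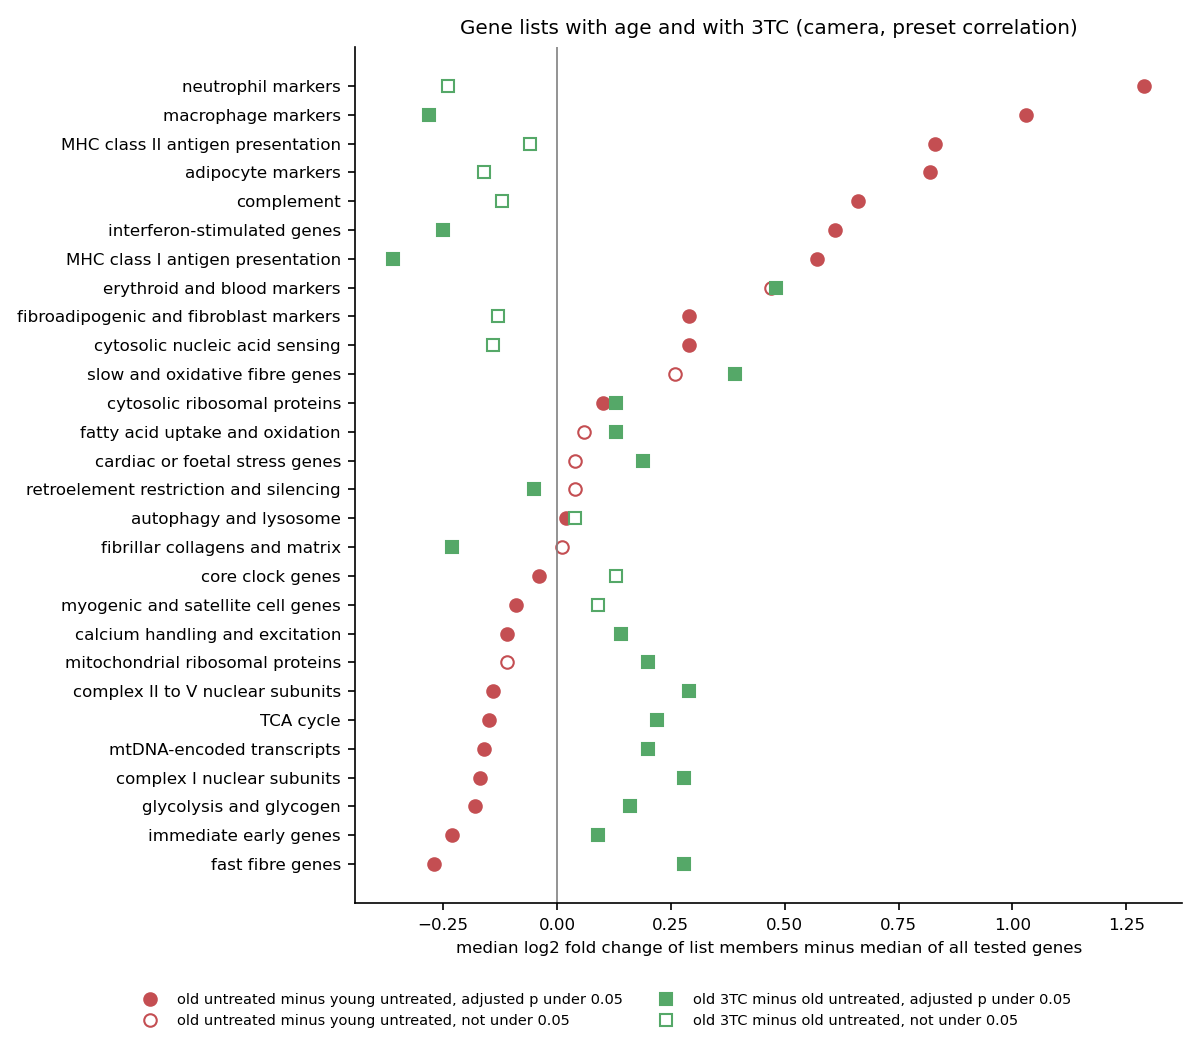
Median log2 change of each gene list minus the median of all tested genes, with age (circles) and with 3TC (squares); filled marks have a camera adjusted p under 0.05 at the preset correlation. Macrophage markers lie at 1.03 with age and at −0.28 with 3TC; with an estimated correlation 0 lists pass in either comparison.

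Old mice given 3TC differed from old untreated mice in no gene past the threshold. The smallest p among decreases belonged to Zmat3, a p53 target, at 822 ± 83.6 in old untreated and 573 ± 103 in old 3TC mice (−0.53 ± 0.12), and to Pml, the gene of nuclear body scaffolds, at 680 ± 66.9 and 472 ± 64.4 (−0.53 ± 0.12), followed by Trps1 (−0.40), Agap1 (−0.40) and Tmem88b (−1.06 ± 0.26). All 6 old 3TC libraries lay below the old untreated mean for Zmat3 and Pml, which were picked for a small p in these same libraries. Adjusted over the list alone, 1 of 26 p53 targets fell, Zmat3, in a list that camera did not call (adjusted p = 0.0644). Tcap, the gene of the sarcomere protein telethonin, was at 0.29 ± 0.11, with Rpp25l (0.23), Usp2 (0.32), Lcmt1 (0.17) and Nusap1 (0.77) the others among increases. By limma 0 of 16060 genes passed, 1633 had an unadjusted p under 0.05 where chance gives 803, and the lowest adjusted p was 0.4805. By edgeR and by DESeq2 0 passed as well.

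Lists of mitochondrial and contractile genes lay above the all-gene median with 3TC, which was itself at −0.15 and near 0 under median-of-ratios scaling. Complex I genes lay 0.28 above it (Ndufa13 0.18, Ndufa12 0.13) and genes of complexes II to V 0.29 above it (Cox6a2 0.23, Uqcrb 0.18), each at camera adjusted p = 4.77e-22, or 0.523 with an estimated correlation. Mitochondrial ribosomal protein genes (0.20, Mrpl23 0.14, Mrpl28 0.21, adjusted p = 4.64e-12), fast fibre genes (0.28, Pgam2 0.18, Mylpf 0.20, adjusted p = 1.88e-08), TCA cycle genes (0.22, Idh3a 0.14, Fh1 0.12, adjusted p = 6.04e-08) and glycolysis genes (0.16, adjusted p = 0.00029) lay above as well, although Pgm1 (−0.42) and Hk1 (−0.32), the members of the glycolysis list with the smallest p, were below 0, as was the list mean (−0.02). These 6 lists kept the call in all 18 fits that left out a library, but none passed with an estimated correlation, at adjusted p = 0.566 for the TCA cycle and 0.523 for the others. TCA cycle genes gave adjusted p = 0.175 with the liver and brain scores as covariates.

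Other lists above the all-gene median with 3TC rested on fewer libraries, and none passed with an estimated correlation. Slow fibre genes lay 0.39 above it (Myh7 1.20 ± 1.17, Tnnt1 0.96 ± 1.12, adjusted p = 1.37e-05) and gave adjusted p = 0.171 without old 3TC female 8. Blood markers lay 0.48 above (Hba-a1 0.40, which shares reads with Hba-a2, but Ppbp −0.76 and Pf4 −0.38, adjusted p = 0.00172, or 0.0792 without old 3TC female 8), mtDNA-encoded genes 0.20 above (mt-Nd1 0.12, mt-Cytb 0.11, adjusted p = 0.000295, or 0.166 without old 3TC female 4) and cardiac genes 0.19 above (Myh6 0.92, adjusted p = 0.0153, or 0.287 without old untreated female 2). Calcium-handling genes lay 0.14 above (Camk2d −0.24, Fkbp1a −0.12, adjusted p = 0.00385, or 0.157 without old untreated male 6), ribosomal protein genes 0.13 above (Rpl3 −0.41, adjusted p = 0.00385, or 0.299 without old untreated male 1), fatty acid oxidation genes 0.13 above (Ppard −0.22, Ppara 0.38, adjusted p = 0.0142, or 0.676 without old 3TC female 8) and immediate early genes 0.09 above (Klf4 −0.52, Klf2 −0.40, adjusted p = 0.0427, or 0.308 without old 3TC female 4). The own medians of these last 4 lists, −0.01, −0.02, −0.02 and −0.07, were below 0, opposite to the test. These 8 calls were lost in 1 to 8 of the 18 fits that left out a library, and the values given are the highest. At an estimated correlation they gave adjusted p = 0.523 to 0.894. With the liver and brain scores as covariates only slow fibre and ribosomal protein genes of these lists passed (adjusted p = 0.0312 and 0.0108), and under median-of-ratios scaling only mtDNA-encoded, calcium-handling and ribosomal protein genes did (0.00829, 0.000697 and 2.86e-09).

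Some immune lists and a matrix list lay below the all-gene median with 3TC by camera at the preset correlation, and none passed with an estimated one. Of the immune lists called for age, MHC class II (camera adjusted p = 0.627), complement (0.57), nucleic acid sensing (0.0785) and neutrophil markers (0.764) were not called with 3TC. MHC class I genes lay at −0.36 (H2-Q7 −0.88 ± 0.30 and H2-Q6 −0.91, which share reads, adjusted p = 1.72e-05). They gave adjusted p = 0.83 with an estimated correlation, although the preset one kept the call in all 18 fits that left out a library. Interferon-stimulated genes lay at −0.25 (Ifi35 −0.35, Ifi44 −0.88, adjusted p = 0.0128, or 0.448 without old untreated female 1), macrophage markers at −0.28 (Ms4a7 −0.86, Cx3cr1 −1.08, adjusted p = 0.0305, or 0.461 without old untreated male 6) and collagen and matrix genes at −0.23 (Lox −0.57, Mmp14 −0.43, adjusted p = 0.0128, or 0.392 without old 3TC male 1). Genes that silence retroelements lay at −0.05 (Fam208a −0.34, Dnmt1 −0.33, adjusted p = 0.0142, or 0.0896 without old untreated male 1). These 4 calls were lost in 3 to 5 of the 18 fits. The 19 lists called for 3TC, 14 up and 5 down, had 0 members past the threshold over all genes or when adjusted over the list alone. The 4 lists called below other than MHC class I gave adjusted p = 0.894 with an estimated correlation. With the liver and brain scores as covariates, interferon-stimulated genes and macrophage markers gave adjusted p = 0.886 and retroelement silencing genes 0.146.

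The 25 genes named in advance gave 0 calls by limma for age (lowest adjusted p = 0.0564, Irf7), for 3TC (0.486, Tmem173, the gene of STING) and between old 3TC and young mice (0.43, Il6). For age, 14 of them lay above 0. The cell cycle inhibitors of senescent cells stood at 2.13 ± 1.01 for Cdkn2a and 0.70 ± 0.34 for Cdkn1a, and with 3TC at −1.85 ± 1.01 and −0.25. Cdkn2a was near the floor, at 4 to 72.8 normalised counts in old untreated and 0 to 103.1 in old 3TC libraries. Il6 was near it too, at 2.6 to 19 and 0 to 6.5 in the same order. The log2 changes of both with 3TC thus rest on low counts, and for Cdkn2a the highest value was in an old 3TC library. Interferon genes with age were Isg15 at 0.86 ± 0.28 and Ifit1 at 0.51, and with 3TC −0.19 and −0.24, with Irf7 at −0.49. Of the nucleic acid sensors and nucleases, Tmem173 stood at 0.72 and −0.53, Mb21d1 (cGAS) at −0.18 and −0.44, Samhd1 at 0.57 and −0.27 and Trex1 at 0.13 and −0.16. Genes of mtDNA upkeep and nucleotide supply were Tfam (−0.04 and 0.03), Polg (0.31 and −0.18), Dck (0.09 and −0.28) and Tk2 (0.60 ± 0.17 and −0.18). Genes of atrophy, denervation and regeneration were Fbxo32 (0.29 and −0.43), Trim63 (−0.01 and 0.08), Myog (0.65 and 0.01), Chrng (1.59 ± 0.94 and −0.12) and Pax7 (−0.76 and 0.17), and the remaining genes were Ppargc1a (−0.10 and 0.04), Gdf15 (−0.04 and −0.33), Il6 (−0.82 and −1.11), Col1a1 (−0.32 and −0.56), Col3a1 (−0.29 and −0.51), Myh7 (−0.04 and 1.20) and Myh4 (−0.06 and −0.01).

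The age and 3TC changes were compared across genes, which are not independent replicates and share the old untreated libraries. Of the 59 age genes, 53 (89.8%) had a 3TC change of the opposite sign, 49 of 59 did so relative to the all-gene medians, and limma called 0 of them for 3TC. Pearson's r over 16060 genes was −0.43 and Spearman's rho −0.46, where simulated arms without an effect gave r = −0.48 on average (SD 0.19), and 69 of 100 draws were as low. The covariance was −0.095 against −0.094 simulated. With the old untreated libraries divided between the comparisons, so that these shared none, r averaged −0.14 over 18 splits, and the share of age genes with the opposite sign had a median of 50% and ran from 0 to 100%. These splits called a median of 2.5 age genes, with at most 122 and 94 of them opposite, so many of these shares rest on 2 genes. A reversal by 3TC beyond the shared libraries was not detectable. Leaving out single libraries moved r from −0.56, without old 3TC female 4, to −0.09, without old 3TC male 2.

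Old mice given 3TC still differed from young mice in Ide, the gene of the insulin-degrading enzyme (chromosome 19, 37268743 to 37337852), at 13000 ± 1240 against 6410 ± 890 (1.03 ± 0.10, 2.04-fold, adjusted p = 0.000171, limma), and in Btaf1, a regulator of TATA-binding protein (36926079 to 37012752), at 1750 ± 315 against 876 ± 101 (0.98 ± 0.12, adjusted p = 0.00105). Both were also higher in old untreated than in young mice (Ide 1.02 ± 0.10, Btaf1 1.16 ± 0.12, each at adjusted p = 9.34e-05, limma). The lowest of the 12 old libraries stood at 1.65 times the highest of 6 young ones for Ide and at 1.39 times for Btaf1. Fgfbp3 (36917550 to 36919615), named after its values were seen, was higher in old untreated mice (1.02 ± 0.21, adjusted p = 0.0454, limma). Cpeb3 (37021291 to 37208601), between Btaf1 and Ide, was at 0.03 ± 0.16. Age cannot be told apart here from a difference in the genome between the old and the young cohort. Ide and Btaf1 were the only genes called between old 3TC and young mice by limma, where DESeq2 called 120. The count rose to 16 without young untreated female 8, 5 without old untreated female 1, and 4 without old untreated male 6, old 3TC female 4 or young untreated male 8.

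**Figure D4:**
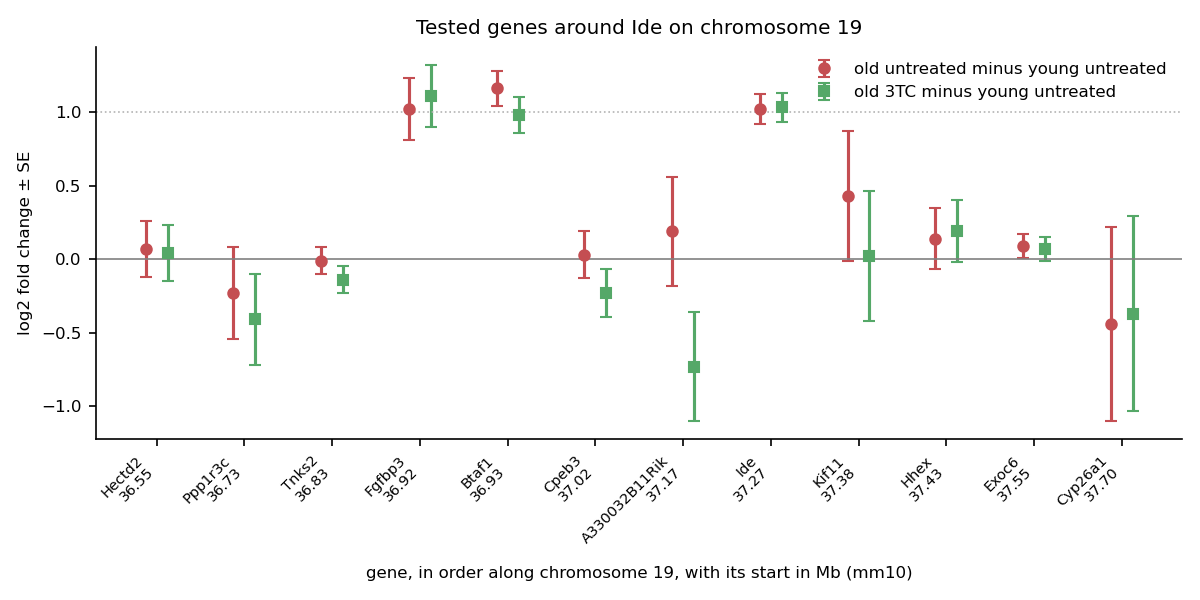
Log2 change ± SE of tested genes around Ide, in order along chromosome 19 (mm10), for old untreated (circles) and old 3TC mice (squares) against young mice. Fgfbp3, Btaf1 and Ide lie near 1 in both, and Cpeb3 lies at 0.03 with age.

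Between old 3TC and young mice 22 lists were called by camera at the preset correlation, 19 up and 3 down, whereas 0 passed with an estimated correlation (lowest adjusted p = 0.4738), 0 by fry and 0 by the score per library. Ribosomal protein genes lay 0.23 above all genes, with 48 of 50 risen when adjusted over the list alone (adjusted p = 5.91e-33), macrophage markers 0.74 above with 6 of 26 (adjusted p = 9.72e-11), complement 0.62 above with 7 of 21 (adjusted p = 2.87e-09), MHC class II genes 0.81 above with 8 of 10 (adjusted p = 9.88e-06), blood markers 0.94 above with 7 of 10 (adjusted p = 0.000262) and interferon-stimulated genes 0.33 above with 0 of 40 (adjusted p = 7.01e-05). Immediate early genes lay at −0.31 with 2 of 27 fallen (adjusted p = 0.000148), and collagen and matrix genes (−0.26, adjusted p = 0.0113) and tendon markers (−0.27, adjusted p = 0.0383) lay below as well.

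Females differed from males in 374 genes, 106 higher and 268 lower in females. Beside Xist (10.49 ± 0.41) and its antisense gene Tsix (7.83), whose reads cannot be told from those of Xist because the strand was not stated, the largest increase was Cyp3a41a (6.05 ± 1.32, adjusted p = 0.0187, limma), a cytochrome of female liver. The largest decreases were the Y-linked genes Ddx3y (−11.33), Eif2s3y (−10.61) and Kdm5d (−9.38), with Uty at −8.79. Adding the same scores as covariates left 189 genes by limma, and the count was 243 without old untreated male 3. Without old 3TC male 2, the library with the highest liver score, 474 genes passed, 253 higher and 221 lower in females. The excess of lower genes was then lost.

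Within a sex the changes were tested on 3 against 3 libraries. In males limma called Ide (1.22 ± 0.14, adjusted p = 0.00246) and Btaf1 (1.17 ± 0.18, adjusted p = 0.0447) for age, where females had 0.83 ± 0.14 and 1.14 ± 0.18, each at adjusted p = 0.1004. In females limma called 0 genes for age (2644 at an unadjusted p under 0.05; edgeR 0, DESeq2 57). With 3TC limma called 0 in females (1286 at an unadjusted p under 0.05; edgeR 0, DESeq2 32) and 0 in males (583; edgeR 0, DESeq2 149). No gene differed between the sexes in its age change by limma (783 at an unadjusted p under 0.05; edgeR 0, DESeq2 152) or in its 3TC change (477; edgeR 0, DESeq2 71). Leaving out single libraries moved the age count in females to 17 without old untreated female 3 and to 1 without young untreated female 8. In males it moved to 37 without young untreated male 8, to 5 without young untreated female 3, and to 1 without any of old untreated female 3, male 1, male 3 or male 6, old 3TC female 4, female 8 or male 5, or young untreated male 1 or male 2. The 3TC count in females moved to 2 without young untreated male 8.

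Transcripts encoded by mtDNA held 21.8 ± 6.95% of normalised counts in young, 21.5 ± 3.62% in old untreated and 22.6 ± 3.73% in old 3TC mice (n = 6 each). The differences, −0.305 percentage points with age and 1.08 with 3TC, were within the spread between libraries (exact two-sided permutation p = 0.933 and 0.621; adjusted over 14 tests 0.942 and 0.724). The age difference was 2.33 without young untreated male 2 and −1.54 without old untreated male 6. The 3TC difference also moved widely when single libraries were left out but kept its sign, with the range given below under the processing.

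Transposable-element subfamilies, of which the LINE, SINE and LTR classes are copied through reverse transcription and the DNA class is not, were tested after the data were seen. The subfamilies named here were chosen after their values were seen. They held 4.26 ± 4.15% of counts in young, 2.01 ± 0.126% in old untreated and 1.78 ± 0.143% in old 3TC mice (n = 6 each). Young untreated females 1 and 3 stood at 5.92% and 12.04%; without them the young mean was 1.90 ± 0.428% (n = 4). The age difference of −2.25 points had an exact two-sided permutation p of 0.329 (adjusted 0.567) and turned to 0.111 without these females. The 3TC difference of −0.229 points had an exact two-sided permutation p of 0.013 and did not pass over 14 tests (adjusted 0.091). The median 3TC change of subfamilies was −0.21 where that of all genes was −0.15, so part of the fall was shared with genes. Under median-of-ratios scaling the subfamily median was −0.08, with 317 above and 651 below 0. Of 968 subfamilies limma called 0 for age (66 at an unadjusted p under 0.05; edgeR 0) and 0 for 3TC (8; edgeR 0). Without these females it called 0 in both as well, with 74 and 97 at an unadjusted p under 0.05. Between old 3TC and young mice limma called 0 (304 at an unadjusted p under 0.05) and edgeR 316. The median change by limma was −0.71, and −0.04 without these females. The LINE subfamily L1Md_A was at −0.53 ± 0.30 with age and 0.02 without these females, and at −0.06 ± 0.30 with 3TC, IAPEz-int, an endogenous retrovirus, at −0.01 ± 0.22 and −0.25 ± 0.22, and MMTV-int at 1.71 ± 0.46 and 0.01 ± 0.46.

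**Figure D5:**
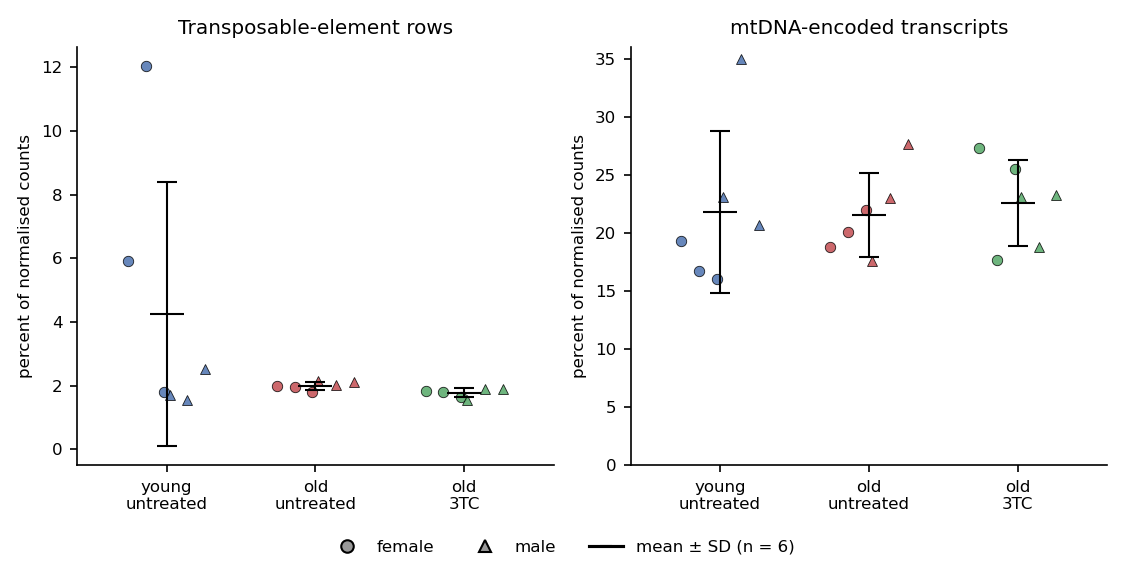
Percent of normalised counts in transposable-element subfamilies (left) and in mtDNA-encoded transcripts (right) in each library, by arm. Circles are females, triangles are males and bars are mean ± SD (n = 6); young untreated females 1 and 3 lie at 5.92% and 12.04% in the left panel.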

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

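All tests of explanations in this part, and the gene lists behind them, were chosen only after the result was seen.

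Liver transcripts were present in some libraries of every arm. An effect of age or 3TC alone is argued against by libraries of a single arm and sex, which differed by up to 10.93. The liver score was 2.21, 2.67 and 11.27 in old 3TC females and 1.99, 3.56 and 12.92 in old 3TC males. In old untreated libraries it was lower than in young ones within sex, by −3.68 (exact two-sided permutation p = 0.01). A part of age in that lower score cannot be told apart from liver RNA in some libraries. A single common liver source is argued against by the difference between female-biased and male-biased liver genes, which was 4.85 ± 2.47 in females and −1.28 ± 2.89 in males (n = 9 each, exact two-sided permutation p = 0.000576). Another candidate explanation that remains open is liver RNA from animals of the same sex as the library, for which that difference of 6.13 between the sexes is in line with what the test asked, and 7 of 9 females lay above the highest male. With the liver and brain scores as covariates the age count went from 59 to 4. The median size of the 59 changes went from 0.98 to 0.84 and their median SE from 0.18 to 0.19. All 59 kept their sign, which genes chosen for a large change could hardly lose. The count alone therefore does not tell for or against liver RNA.

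The share of counts in transposable elements stood apart in young untreated females 1 and 3, at 5.92% and 12.04% where the highest other library had 2.52%. A single class of elements switched on is argued against by the LINE, SINE, LTR and DNA classes, whose 8 values in these libraries all lay above the highest of the other 16. Reads from genomic DNA or unprocessed RNA may account for it: summed counts of families normally silent in muscle were raised in both, with a lowest ratio of 1.09 to the highest other library (olfactory and vomeronasal genes 910.4 and 1548.1 against 837.2). An effect of young age in females cannot be told apart, since only young untreated female 8, at 1.82%, bears on it.

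Ide, Btaf1 and Fgfbp3, neighbours on chromosome 19, were near 2-fold higher in old untreated than in young mice, and Ide and Btaf1 also in old 3TC mice, where Fgfbp3 did not pass (1.11 ± 0.21, adjusted p = 0.0974, limma). A single extra copy of the whole stretch is argued against by Cpeb3, inside it, at 0.03 ± 0.16 with age. A difference in the genome between the old and the young cohort (lowest old over highest young value 1.65 for Ide) and regulation by age (1.39 for Btaf1) cannot be told apart, because every old mouse may come from another cohort than the young ones. Of 16060 genes, 24 separated the 12 old from the 6 young libraries, 22 of them higher in old, where chance gives 1.73.

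The age count is larger than other splits of the samples gave: 59 genes against a highest other of 8. For the sexes it was 374 genes against a highest other of 33. In both, the 1 of 100 splits as large was the real one, the smallest share possible. A chance split is thus an unlikely source of these counts, in a test chosen after they were seen. The test does not tell age from other differences between the arms, such as the liver score. Without young untreated females 1 and 3 the age count was 2. Chance remains open for the count of old 3TC against young, with 2 genes against a highest other of 168 and 6 of 100 splits as large. That says nothing against Ide and Btaf1 themselves (adjusted p = 0.000171 and 0.00105, limma). Where the real count was 0, all 100 of 100 splits are as large by construction and say nothing about chance: this holds for 3TC (1633 genes at an unadjusted p under 0.05 by limma; edgeR 0, DESeq2 0), where the highest other was 253, and for the differences between the sexes in the age and the 3TC change (783 and 477; edgeR 0, DESeq2 152 and 71), where it was 82 and 85. That other splits called this many genes points to a structure of the samples apart from the arms. The first principal component, the axis of largest variance between libraries (32.7%), ran largely with the liver score. It went from −93.9 in young untreated female 3 (score 11.19) to 66.8 in old untreated male 3 (1.51). The next component was highest, at 85.3, in young untreated male 8, which had the highest brain score (8.94). Whether such RNA gave rise to the calls of these splits was not tested. Within a sex the 10 splits are too few for a share under 0.05: age in males had 2 genes against a highest other of 0, with 1 of 10 as large, and age in females and 3TC in either sex had 0 against 0, with 10 of 10 as large.

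Single libraries stood far from the others of their arm in 28 of 372 groups, where the rule for it, the gap to the nearest library over the range of the arm at the level of Dixon's test, by chance flags about 1 in 20 groups, or 19. Old untreated female 1 held 7 of them: Myl1 at 213066, Ifi44 at 275, Pgam2 at 67874, Ppard at 4547, Trex1 at 2251, Col1a1 at 1489 and Col3a1 at 2367 normalised counts. Other old untreated libraries stood apart for Nr4a2 (male 3, 63.3), Pml (female 3, 550), Ppbp (female 3, 3.73), Myh7 (male 1, 21.8) and Mb21d1 (male 6, 90.6). Among old 3TC libraries these were Cd74 (female 8, 5306), Nusap1 (male 5, 47.7), Ppara (female 5, 766), Gdf15 (male 1, 0) and Fbxo32 (male 1, 37785). Young untreated male 2 stood apart for Casq1 (120341), Uqcrb (19829), Myh4 (1079789), Ide (4724) and the mtDNA-encoded share (35.0%). Young untreated female 3 stood apart for S100a8 (1.09), H2-Q6 (106), Mmp14 (509) and Col1a1 (2349), and young untreated male 8 for Hpgds (137) and Samhd1 (2109).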

How the results depend on the processing

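The settings chosen only after the data were seen were leaving out young untreated females 1 and 3, the liver and brain scores as covariates, the total over gene rows, the list score per library, the test of the scores within sex and edgeR without the pair of libraries whose step lay near 1. Over the genes named, 8179 values under alternatives kept their side of the threshold, 160 passed newly and 297 no longer passed. Of these values 0 were labelled as reversed, which does not show that changes near 0 kept their sign. The 3TC count stayed at 0 under every alternative run (1633 at an unadjusted p under 0.05 by limma; edgeR 0, DESeq2 0). Where a value moved, the cause was not tested, except that fits with fewer libraries also have fewer degrees of freedom. At 64.2 M to 85.4 M reads per library, genes with a mean under 10 normalised counts were not tested, so nothing is said of them.

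The age count was 40 with the young and old untreated arms alone (12 higher, 28 lower), 24 under median-of-ratios scaling (21 of them opposite with 3TC), 14 without a sex term, 4 by edgeR, 221 by DESeq2, 991 with array weights and 985 at an adjusted p under 0.1. Of the lists, 0 passed for age and 0 for 3TC with an estimated correlation, fry called 17 for age and 0 for 3TC, and the score per library called 5 for age and 0 for 3TC. The correlation of the age and 3TC changes was −0.14, and 2 age genes were opposite, when the old untreated libraries were divided between the comparisons.

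Between old 3TC and young mice the count was 120 by DESeq2, 8 with array weights, 6 after quantile normalisation, 4 with these arms alone and 9 at an adjusted p under 0.1. The sex count was 954 by DESeq2 and 722 with array weights. Within a sex, no filter gave 10 genes for age in females, 2 for 3TC in females and 1 for 3TC in males. DESeq2 gave 57 and 183 for age in females and males, 32 and 149 for 3TC, and 152 and 71 for the differences between the sexes. Array weights gave 1491 and 393 for age in females and males and 2587 for 3TC in males. For age in males the count was 7 after quantile normalisation and 1 under median-of-ratios scaling, without a trend, by edgeR and with the total over gene rows.

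Without young untreated females 1 and 3 the counts were 2 for age (1 of them opposite with 3TC), 136 for sex, 1 and 5 for age in females and males, and the age difference in transposable-element share turned to 0.111; with median-of-ratios scaling as well the age count was 3. With the liver and brain scores as covariates the counts were 4 for age, 4 for old 3TC against young, 189 for sex, 52 for age in males and 2 for the difference between the sexes in the age change, and 12 lists were called for 3TC. By edgeR without the pair of libraries with a step near 1, the counts were 2 for age, 5 for old 3TC against young and 1 for age in males.

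Leaving out each library in turn gave 2 to 608 genes for age, 0 to 0 for 3TC, 2 to 16 for old 3TC against young, 243 to 507 for sex, 0 to 17 and 1 to 37 for age in females and males, and 0 to 2 for 3TC in females. It gave 15 to 26 lists for age, 13 to 23 for 3TC, a correlation of −0.56 to −0.09, and 1 to 594 age genes opposite with 3TC. The mtDNA-encoded share differed by −1.54 to 2.33 points with age and by 0.139 to 2.31 with 3TC, and the transposable-element share by −2.79 to −0.693 and by −0.27 to −0.186.

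With the replicate numbers as a block the age count was 6 and the count for old 3TC against young was 0 (2 without the block). The pairing check found correlations of deviations between libraries with the same number of 0.11, 0 and 0.17 for old untreated against young and of 0.19, −0.01 and −0.06 for old 3TC against young, so the numbers do not pair the animals. No paired analysis was possible for 3TC because the old 3TC and old untreated arms share a single number, male 1.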

Other observations

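The tests of gene lists between the sexes were chosen only after the data were seen.

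Lists of immune and matrix genes had medians below 0 in females against males at the preset correlation of camera, although none of them passed with an estimated correlation (adjusted p = 0.327 to 0.905) and few of their members passed. Of 26 macrophage markers 4 were lower in females past the threshold over all genes (Fcgr1, Adgre1, Fcer1g and Cd163), with a list median of −0.84 (camera adjusted p = 1.17e-12). Complement genes (2 of 21 lower) had a median of −0.66 (adjusted p = 7.28e-09), MHC class II genes −0.79 (adjusted p = 7.15e-06), T and NK cell markers (1 of 17 lower) −0.78 (adjusted p = 0.000999) and collagen and matrix genes (3 of 34 lower) −0.42 (adjusted p = 1.09e-06). Fibroblast markers had a median of −0.27 (adjusted p = 0.000305), endothelial markers −0.21 (adjusted p = 0.000999) and genes of senescence −0.35 (adjusted p = 0.00463).

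Genes of polyamine and NAD metabolism had a median of −0.12 in females against males, with Amd1, Nmrk2, Smox and Odc1 lower past the threshold (camera adjusted p = 0.00125). Ribosomal protein genes had a median of 0.08 (adjusted p = 1.23e-08) and proteasome genes of 0.11 (adjusted p = 9.02e-05). With an estimated correlation the sex chromosome genes alone passed (adjusted p = 0.000528), while polyamine and NAD genes gave adjusted p = 0.232 and ribosomal protein and proteasome genes adjusted p = 0.905. Liver transcripts differed between the sexes as well: the female-biased minus male-biased liver score lay above the highest male in 7 of 9 females.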
